A study of Mus musculus with 16 samples.

How the data were processed

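RNA from 16 samples of TUBO cells was hybridized to Illumina mouse BeadChips as biotin-labelled cRNA, 1 array per sample. The samples fall into 6 groups by inhibitor and time. The groups are the negative control hairpin inhibitor (labelled scrambled) and anti-miR-135b, each at 24 h (n = 2), 48 h (n = 3) and 72 h (n = 3), all at 200 nM. Per the labels, cells were transfected with Lipofectamine and RNA was isolated with a kit that keeps small RNA. No label says whether replicates of a group came from separate cultures or transfections. The p-values therefore measure the spread between these samples.

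The deposited table of non-normalized values holds the bead-averaged intensity of 25697 probes on each array. GenomeStudio was used to make it, per the submitters' processing notes, and its version is not given in the sources used here. All values are above 0 and the array medians differ, from 281.2 to 346.8, so neither background subtraction nor normalization between arrays was found in them. The authors' deposited value table holds log2 values of these arrays, normalized by a method that is not given in the sources used here. Its scale was taken from the values, and its direction from ranks. All 16 of its columns ranked the probes most like the array of the same sample (Spearman's rho of 0.999 or more), and its column medians lay between 8.24 and 8.26. It was used as an alternative only. No detection p-values and no control probes came with the intensities used here, so a filter on detection and a background from control probes were not possible.

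From the intensities, background was corrected in limma 3.58.1 (R 4.3.3) by normexp with the saddle method and an offset of 50. The arrays were then quantile normalized on the log2 scale. Background correction widens differences of dim probes and the offset narrows them, so fold changes of dim genes depend on both settings. Probes were kept when their mean over the 16 arrays lay above the median of all probes, a log2 value of 7.1, which left 12848 probes for 9032 named genes. No probe was averaged with another. Gene names came from the platform annotation. It gives 1 symbol for 23978 probes, none for 1719 and several for 0, and the gene IDs of 23962 probes were found in the RefSeq gene table. Probes with no symbol and predicted clones were tested and counted and are not named.

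Each probe was fitted with lmFit and eBayes in 1 model with a mean for each of the 6 groups, which share 1 estimate of the spread (10 residual and 7.8 prior degrees of freedom). Contrasts gave the inhibitor difference at 48 h, at 72 h, averaged over 48 and 72 h, and at 24 h. Further contrasts gave the difference between the inhibitor effects at 72 and 48 h, the change from 24 to 48 h in the control and the change from 24 to 72 h under anti-miR-135b. P-values are two-sided and were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The arrays lay on 2 chips. Both arms at 48 h shared the first chip with the 24 h controls, and both arms at 72 h shared the second with the 24 h anti-miR-135b samples. The contrasts at 48 h and at 72 h and both time contrasts are therefore within 1 chip, and their mean and their difference take nothing from a chip shift. At 24 h chip and inhibitor cannot be told apart. On each chip the control samples of a time took the positions before the inhibitor samples, so position and arm cannot be told apart either. The 24 h samples took the last positions, G and H, of both chips, so position and time cannot be told apart in the time contrasts.

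The comparisons, the tests, the alternatives and 27 gene lists with 649 entries were fixed before the data were examined. Lists were tested with limma's camera (preset correlation between genes of 0.01, two-sided) on the brightest kept probe of each gene, adjusted over the 23 lists that had at least 5 measured genes. Each was also tested with a correlation estimated from the data and with fry. The rule for named genes took, for the inhibitor differences at 48 h, 72 h and their mean, the 10 largest changes per direction past the threshold with arrays that do not overlap, or the 5 smallest p-values per direction where none passed. It took 5 per direction in the other contrasts, up to 4 members of a described list by smallest p, and always Mid1, Mtch2, Lemd1 and Mir135b. No probe named Lemd1 or Mir135b was in the tables used here. Exact permutation tests rearranged the samples between arms within each time, two-sided.

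The steps were tested on simulated data with the spread of these arrays and 12848 probes. Of 2-fold changes, 56.2% were called at 48 h, 84.4% in the mean of 48 and 72 h, 31.6% at 24 h and 43% from 24 to 72 h under the inhibitor. Of 4-fold changes, 96.6%, 99%, 91.6% and 92.4% were called. False calls made up 3.8% to 5% of calls. Each run held 50 changed probes of each simulated size, from 1.41-fold to 4-fold. The adjustment is stricter where fewer probes change, so a lone change would be called less often than these rates. A count of 0 calls therefore does not exclude 2-fold changes. Camera called a list of 25 simulated genes shifted by 0.3 in 20 of 20 runs and unshifted lists in 2 of 400. The simulated probes were drawn independently. These camera rates therefore do not carry over to lists whose genes vary together, such as the interferon list below.

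The alternatives were no background correction, an offset of 16, median scaling, cyclic loess, the authors' value table, no filter and a stricter filter on dim probes (above the 70th percentile, 7709 probes). They also covered a fit of only the groups compared, a trended and robust prior, array weights, leaving out each array, and for lists the mean of a gene's probes, fry and an estimated correlation. A fit with a block by label number and a fit without the least alike array of each group of 3 were added after seeing the data, as were the exact tests of list means and the camera tests of inhibitor differences between 24 h and the later times and 2 further gene lists, on NRF2 targets and on clock genes. Chip as a random block could not be fitted, since each group lies on 1 chip. A planned test of transcripts with a miR-135 seed match was not run, because no 3' UTR sequences were among the references used here.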

Results

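The series asked which transcripts respond when miR-135b is silenced in a mammary carcinoma driven by ErbB2. TUBO is a cell line from a mammary tumour of BALB-neuT mice, which carry an activated rat ErbB2 (neu) transgene. The cells were transfected with 200 nM of a hairpin inhibitor of miR-135b (anti-miR-135b) or of a negative control hairpin, and RNA was profiled on Illumina bead arrays. There were 2 samples per arm at 24 h and 3 per arm at 48 h and at 72 h, 16 in all. The median probe intensity per array ran from 281.2 to 346.8 and the upper quartile from 375.8 to 529.4. Values below are normalized log2 intensities, and differences are anti-miR-135b minus control unless a time course is named.

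Mid1, a microtubule-associated ubiquitin ligase, and Mtch2, a carrier-like protein of the outer mitochondrial membrane, are the miR-135b targets that the study names. At 72 h Mid1 measured 7.79 ± 0.62 (SD, n = 3) under anti-miR-135b and 6.7 ± 0.19 (SD, n = 3) in the control, a difference of 1.09 (SE 0.25) or 2.13-fold. At 48 h it measured 7.36 ± 0.22 against 6.93 ± 0.18 (SD, n = 3 each), a difference of 0.44 (SE 0.25). At both times every anti-miR-135b sample lay above every control sample. The margin at 48 h was slight, with 7.11 in anti-miR-135b sample 13 and 7.08 in control sample 4. Before normalization their intensities lay in the reverse order (278.6 and 289.6). The exact p given next rests on this separation. Averaged over 48 and 72 h the difference was 0.76 (SE 0.18), 1.7-fold, with an exact permutation p of 0.005, the smallest that 400 arrangements can give. Over all probes tested this did not pass, with a limma adjusted p of 0.24 for the mean and 0.42 at 72 h. A block by label number, added after seeing the data and not given by the labels, changed both calls. Its values are given with the processing below. Without anti-miR-135b sample 18, the lowest of its group (7.08 against 8.24 and 8.06), Mid1 passed at 72 h (1.45, limma adjusted p = 0.036). Without any other single sample at 72 h it did not pass, with differences from 0.87 to 1.15 (limma adjusted p from 0.29 to 0.98). The difference at 72 h was 0.56 with no background correction. It was 0.54 in the authors' value table and 1.41 with the offset of 16. Adjusted over the list alone, the list being Mid1 and Mtch2, the limma adjusted p for the mean was 0.00086, and since the study named both genes this is not independent evidence. At 24 h the difference ran the other way, at -0.62 (SE 0.3, limma adjusted p = 1), with 7.67 ± 0.02 against 8.29 ± 0.08 (SD, n = 2 each), across chips. The Mid1 probe was dim, at the 62.2 percentile of signal averaged over all arrays. Its control means at 48 and 72 h lay below the filter value of 7.1. Its control intensities at 72 h (247.9, 286.7 and 292) lay below the medians of those arrays (303.1, 320.6 and 324.3). The fold change is thus taken from a control level not shown to lie above background.

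Mtch2 had 3 probes, which did not share a direction. ILMN_2610204 was higher by 1.05 (SE 0.31) at 72 h and by 0.64 (SE 0.22) in the mean of both times, with an exact permutation p of 0.03 and a limma adjusted p of 0.49. Without control sample 7 these differences were 0.6 and 0.41. They were 0.64 and 0.39 in the authors' value table and 0.69 and 0.44 with no background correction. The brightest, ILMN_1229238, differed by 0.57 (SE 0.25) at 48 h, by -0.12 (SE 0.25) at 72 h and by 0.22 (SE 0.18) in the mean, with an exact permutation p of 0.36. ILMN_2848583 was lower in the mean by -0.26 (SE 0.18), with an exact permutation p of 0.22. In the main fit none of the Mtch2 probes passed over all probes, and adjusted over the list alone the brightest had a limma adjusted p of 0.22 in the mean. With the block by label number ILMN_2610204 passed at 72 h, as given below. The signs of ILMN_1229238 and ILMN_2848583 at 72 h turned without control sample 9 (0.04 for both) or anti-miR-135b sample 16 (0.03 and 0.07).

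**Figure D1:**
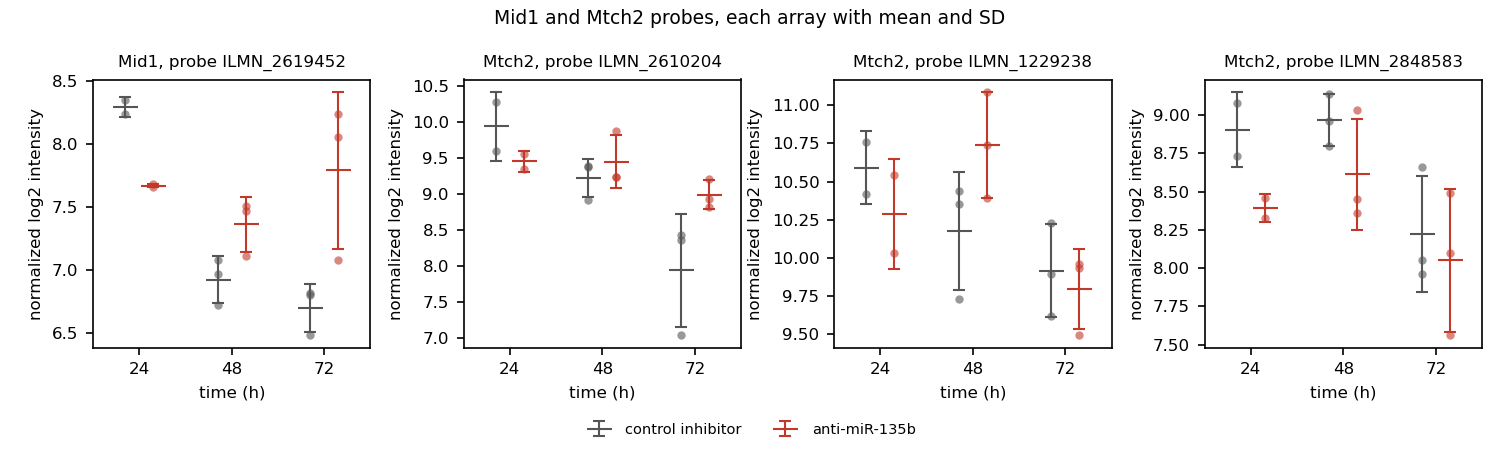
Normalized log2 intensity (y axis) of the Mid1 probe and the 3 Mtch2 probes by time in hours (x axis) in the control inhibitor (grey) and anti-miR-135b (red). Points are arrays, horizontal marks are group means and error bars are SD (n = 2 at 24 h, n = 3 at 48 and 72 h). Mid1 lies higher under anti-miR-135b at 48 and 72 h and lower at 24 h.

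At 48 h the genes with the smallest p for a higher level under anti-miR-135b were Asl, an enzyme of the urea cycle (difference 0.83, SE 0.19), the kinase gene Araf (0.99, SE 0.23), Mak16 (1.03, SE 0.24), Srp54a of the signal recognition particle (1.13, SE 0.27) and Gabra4 (0.9, SE 0.22). Those with the smallest p for a lower level were the transcriptional repressor Zbtb7a (-1.81, SE 0.36), Golga2 (-1.28, SE 0.27), the heterochromatin protein gene Cbx3 (-1.22, SE 0.27), Trps1 (-1.04, SE 0.24) and the checkpoint gene Rad17 (-0.91, SE 0.22). For Golga2, 3 of 4 other probes had the opposite sign. The mean of Cbx3 under anti-miR-135b (6.92) lay below the filter value of 7.1. So did the control means of Asl (6.56) and Gabra4 (6.83). The interferon response list was higher, with 25 of 29 genes positive, a median of 0.3 and a camera adjusted p of 0.0014 (adjusted p = 0.85 with an estimated correlation). Its members with the smallest p were Ddx58, which encodes the RNA sensor RIG-I (0.8, SE 0.24), Ifi35 (0.56, SE 0.3), Psmb9 (-0.38, SE 0.24) and Oas1g (0.76, SE 0.53).

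No probe passed at 48 h. With limma, 0 of 12848 had an adjusted p under 0.05, the smallest being 0.69, and 802 had an unadjusted p under 0.05 where 642 are expected by chance. Without the anti-miR-135b sample 14 at 48 h, 4 probes passed, and the interferon list did not pass without control sample 4 or without anti-miR-135b sample 14 or 15, with list medians from 0.07 to 0.52 over the samples left out.

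At 72 h the genes with the smallest p for a higher level were Smad1, a transducer of BMP signals (1.07, SE 0.18, limma adjusted p = 0.14), Rabgef1 (1.1, SE 0.22), the autophagy kinase gene Ulk1 (0.9, SE 0.2), the splicing factor gene Srsf6 (1.06, SE 0.23) and Commd9 (0.82, SE 0.18). For Smad1, 1 of 2 other probes had the opposite sign. Lower levels with the smallest p were those of Ppp3ca, a catalytic subunit of calcineurin (-1.11, SE 0.23), G3bp2 of stress granules (-0.97, SE 0.2), Suz12 of the Polycomb complex PRC2 (-1, SE 0.22), the desmosomal cadherin gene Dsg2 (-0.85, SE 0.2) and Zmym5 (-0.82, SE 0.21). The interferon response list was again higher by camera, with 22 of 29 genes positive, a median of 0.26 and an adjusted p of 0.017 (adjusted p = 0.76 with an estimated correlation). Tap1 (0.49, SE 0.19), Irf7 (0.58, SE 0.27), Ifih1 (0.52, SE 0.25) and Gbp2 (0.96, SE 0.49) had its smallest p-values. The list of the unfolded protein and integrated stress responses was lower, with 19 of 24 genes negative, a median of -0.35 and a camera adjusted p of 0.019 (adjusted p = 0.49 with an estimated correlation). Among its members Dnajb9 (-0.48, SE 0.17), Hsp90b1 (-0.69, SE 0.29) and Nupr1 (-0.49, SE 0.23) were lower and Sesn2 was higher (0.38, SE 0.21), none past the threshold.

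No probe passed at 72 h either. With limma, 0 of 12848 had an adjusted p under 0.05, and 916 had an unadjusted p under 0.05, of which 577 were higher. Array weights, the authors' value table and no background correction each gave 2 probes, and leaving out anti-miR-135b sample 18 gave 1, which was Mid1. Both lists lost their call without control sample 7 or 8 and without anti-miR-135b sample 17 or 18, with medians over all samples left out of 0.18 to 0.46 for interferon and -0.38 to -0.16 for the stress responses. Neither list passed with median scaling (0.24 and -0.18) or the stricter filter (0.28 and -0.36), nor interferon in the authors' value table (0.12).

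Averaged over 48 and 72 h, genes with the smallest p for a higher level under anti-miR-135b were Alg5 of protein N-glycosylation (0.93, SE 0.18), Commd9 (0.6, SE 0.13), Sqstm1, which encodes the autophagy receptor p62 (0.96, SE 0.22), Mid1 and the mitochondrial protease gene Htra2 (0.64, SE 0.15). For Alg5, 1 of 2 other probes had the opposite sign. Lower levels with the smallest p were those of G3bp2 (-0.81, SE 0.14), Trps1, a GATA-type repressor expressed in luminal mammary cells (-0.92, SE 0.17), Cbx3 (-0.98, SE 0.19), Rbm39 (-0.8, SE 0.15) and Rasa1, a Ras GTPase-activating protein (-0.93, SE 0.19). The lowest limma adjusted p among them was 0.16. The means of Cbx3 under anti-miR-135b, 6.92 at 48 h and 6.89 at 72 h, lay below the filter value of 7.1. The interferon response list was higher, with 27 of 29 genes positive, a median of 0.28 and a camera adjusted p of 2.1e-05 (adjusted p = 0.59 with an estimated correlation and 0.53 with fry). By limma 0 members passed over all probes or adjusted over the list alone. Its mean level was 8.17 ± 0.61 under anti-miR-135b and 7.86 ± 0.3 in the control at 48 h, and 7.93 ± 0.3 and 7.64 ± 0.24 at 72 h (SD, n = 3 each). Ddx58 (0.57, SE 0.17), Tap1 (0.37, SE 0.13), Irf7 (0.45, SE 0.19) and Gbp2 (0.81, SE 0.34) had its smallest p-values.

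The list of miR-135 targets from other studies lay the other way from what release from a microRNA gives, with 11 of 12 measured genes lower, a median of -0.17 and a camera adjusted p of 0.054, which did not pass (adjusted p = 0.57 with an estimated correlation). It passed without control sample 6, 8 or 9 or anti-miR-135b sample 16 (medians -0.19, -0.17, -0.19 and -0.19). It passed too with no background correction (-0.13), the authors' value table (-0.13), the stricter filter (-0.21) and only the groups compared (-0.17). Its members with the smallest p were Siah1a (-0.36, SE 0.17), the TGF-beta receptor gene Tgfbr1 (-0.5, SE 0.24), Stk38l (-0.22, SE 0.15) and the kinase gene Rock1 (-0.28, SE 0.2). The remaining 21 lists did not pass. Among those on invasion, the medians were -0.02 for epithelial junctions and keratins (8 of 16 positive), -0.18 for mesenchymal and EMT genes (3 of 9 positive) and 0.03 for invasion and matrix remodelling (11 of 18 positive). Mammary luminal and basal genes had a median of -0.09, the S phase list 0.04, G2 and M phase 0.05, p53 targets and apoptosis -0.03 and NF-kB and inflammatory genes 0.07. Cholesterol synthesis had a median of -0.08, fatty acid and lipid storage -0.15, unfolded protein and integrated stress responses -0.12, heat shock proteins 0.11, and hypoxia and glycolysis -0.1. Wnt targets had a median of 0.08, TGF-beta and BMP targets -0.03, YAP and serum response targets -0.03, cytosolic ribosomal proteins 0.02 and microtubules and Mid1 partners 0.03. Small RNA machinery had a median of -0.11, and oxidative phosphorylation and mitochondrial carriers both lay at 0. Adjusted over the list alone, 2 epithelial genes and 1 stress gene passed as lower and 1 lipid gene and 1 ribosomal gene as higher. Mid1 passed within the list of its partners (limma adjusted p = 0.0091), by the same probe and unadjusted p as above, so this is not further evidence. Of the leukocyte markers, 0 of 16 with a probe were bright enough to be tested, against 3 of 16 fibroblast and endothelial and 3 of 10 adipocyte markers.

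With limma, 0 of 12848 probes passed for the mean of both times, and 1007 had an unadjusted p under 0.05, of which 493 were higher. Leaving out anti-miR-135b sample 14 at 48 h gave 6 probes and array weights gave 8, while the interferon list had an adjusted p of 0.052, with a median of 0.16, without anti-miR-135b sample 15. A block by label number, added after seeing the data and not given by the labels, called more probes here and at each single time. Its counts are given with the processing below.

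The inhibitor differences at 72 h and 48 h were set against each other next. The genes with the smallest p for a more positive difference at 72 h were Smad1 (1.22, SE 0.26), Fbxo31 (1.07, SE 0.27), Rbm8a (1.13, SE 0.3), Shd (1.05, SE 0.28) and the taste receptor gene Tas2r106 (0.9, SE 0.25). A more negative difference with the smallest p was found for the vomeronasal receptor gene Vmn1r197 (-1.32, SE 0.26), Srp54a (-1.69, SE 0.38), the importin gene Kpna2 (-1.35, SE 0.34), Asah1 (-1.23, SE 0.32, its other probe with the opposite sign) and Atp2b1 (-1.2, SE 0.31). The probes of Tas2r106, Vmn1r197 and Shd were dim, at the 51, 54.2 and 56.5 percentiles of signal, so their expression is not shown to lie above background. With limma, 0 of 12848 probes passed, the smallest adjusted p being 0.85, 706 had an unadjusted p under 0.05, and no list passed. Across probes, which are not independent replicates, the differences at 48 h and 72 h correlated with r = 0.09 and had the same sign for 51.7% of 12848 probes.

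At 24 h the interferon response list was higher in the anti-miR-135b samples, with 28 of 29 genes positive, a median of 0.63 and a camera adjusted p of 3e-12 (adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone, Cxcl10 (1.34, SE 0.35), Bst2 (1.33, SE 0.38), Ifit2 (0.88, SE 0.27) and Ifit3 (0.91, SE 0.29) passed, and 0 passed over all probes. The unfolded protein and integrated stress response list was higher, with 20 of 24 positive, a median of 0.39 and a camera adjusted p of 6.5e-05 (adjusted p = 0.13 with an estimated correlation). Chac1, which encodes a glutathione-degrading enzyme (1.68, SE 0.42), had the smallest p and passed adjusted over the list alone, followed by the transcription factor gene Ddit3 (1.13, SE 0.42), Ppp1r15a (0.87, SE 0.36) and Trib3 (0.89, SE 0.37), which did not. The NF-kB and inflammatory list was higher (18 of 20 positive, median 0.39, camera adjusted p = 0.0061, and 0.56 with an estimated correlation), with Il1a (0.94, SE 0.37), Ccl2 (0.69, SE 0.42, and -0.04 without anti-miR-135b sample 12), Cxcl2 (1.03, SE 0.64) and Ptgs2 (0.35, SE 0.26) at its smallest p-values. Oxidative phosphorylation was lower (30 of 34 negative, median -0.24, camera adjusted p = 6.5e-05, and 0.067 with an estimated correlation), led by Atp5j (-0.67, SE 0.29, 1 of 2 other probes opposite), Uqcrc2 (-0.88, SE 0.38), Ndufa5 (-0.45, SE 0.24) and Ndufb3 (-0.5, SE 0.28), and so was cholesterol synthesis (16 of 18 negative, median -0.24, camera adjusted p = 0.026, and 0.4 with an estimated correlation).

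Single genes at 24 h with the smallest p for a higher level were the glutathione transferase gene Gsta1 (1.41, SE 0.24, limma adjusted p = 0.19), the phosphatase gene Ptpn12 (1.49, SE 0.3), Nt5e, which encodes CD73 (1.09, SE 0.24), Ceacam13 (0.97, SE 0.22) and Sqstm1 (1.61, SE 0.38). Lower levels with the smallest p were those of Pik3r1, the regulatory subunit of PI3 kinase (-1.51, SE 0.3), the mitochondrial ribosomal gene Mrps25 (-0.94, SE 0.25), Exoc2 (-0.79, SE 0.22), Clspn (-0.84, SE 0.24, both other probes opposite) and Wnt5a (-0.96, SE 0.27). Several of these probes were dim, with Wnt5a, Gsta1 and Ceacam13 at the 51.3, 52.5 and 53.5 percentiles of signal. Clspn and Mrps25 lay at the 56.8 and 58.2 percentiles. With limma, 0 of 12848 probes passed and 521 had an unadjusted p under 0.05. The arms lay on different chips at 24 h, so chip and inhibitor cannot be told apart. The NF-kB list did not pass without control sample 2 or anti-miR-135b sample 12, and the cholesterol list did not without control sample 2 or anti-miR-135b sample 11, with medians of 0.23 to 0.77 and -0.25 to -0.19 over the samples left out. With median scaling the NF-kB (0.51), cholesterol (0.01) and oxidative phosphorylation (0) lists did not pass. Nor did NF-kB with the stricter filter (0.43) or cholesterol with cyclic loess (-0.2) or the mean of a gene's probes (-0.22).

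**Figure D2:**
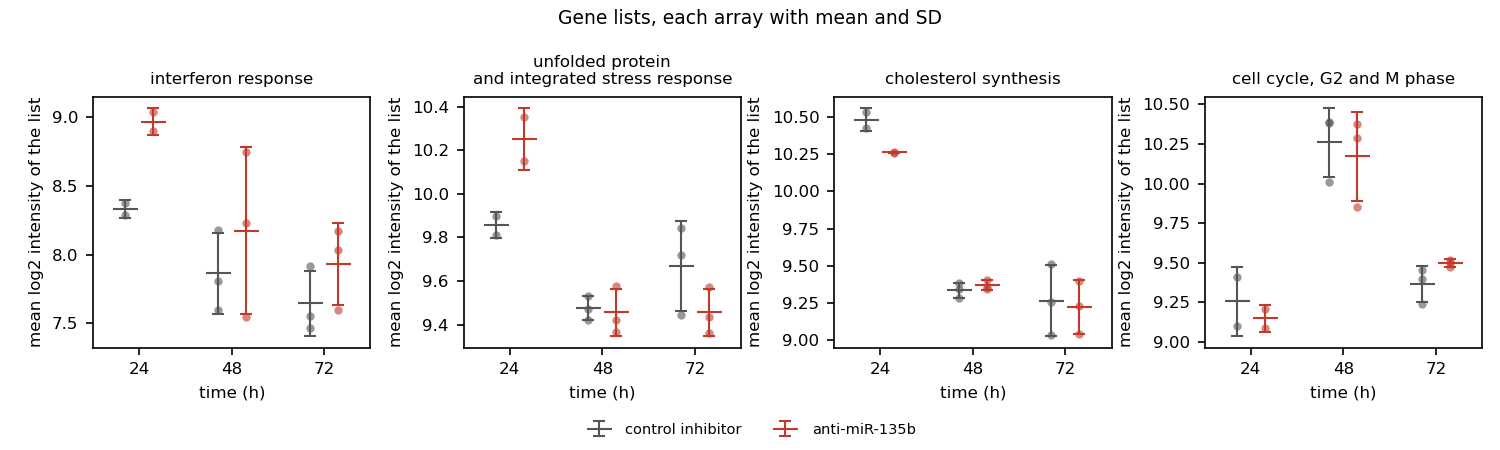
Mean normalized log2 intensity over the measured genes of 4 lists (y axis) by time in hours (x axis) in the control inhibitor (grey) and anti-miR-135b (red). Points are arrays, horizontal marks are group means and error bars are SD (n = 2 at 24 h, n = 3 at 48 and 72 h). The cholesterol list is at 10.48 in the 24 h control and 9.34 in the 48 h control, and the G2 and M list at 9.26 and 10.26.

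In the control arm, cholesterol synthesis genes were lower and cell cycle genes higher at 48 h than at 24 h. Of 18 measured cholesterol synthesis genes 18 were negative, with a median of -1.2 (camera adjusted p = 4.5e-18), and 9 fell past the threshold over all probes and 12 adjusted over the list alone. They include the mevalonate pathway enzymes Mvd, which fell by 2.29 (SE 0.29), and Idi1 (-2.12, SE 0.34), and the later sterol enzymes Hsd17b7 (-1.71, SE 0.26) and Nsdhl (-2.23, SE 0.38). Of 19 G2 and M phase genes 19 were positive, with a median of 1.02 (camera adjusted p = 2.1e-16), and 6 rose past the threshold over all probes, among them the spindle midzone gene Prc1 (1.79, SE 0.27), the checkpoint kinase gene Bub1b (1.23, SE 0.21), Birc5 (1.38, SE 0.25) and the centromere histone gene Cenpa (1.43, SE 0.32). S phase genes were positive in 19 of 20, with a median of 0.74 (camera adjusted p = 8.7e-10, and 0.071 with an estimated correlation), and Rrm2 (1.52, SE 0.23) and Cdc45 (0.97, SE 0.21) rose past the threshold, while Mcm5 (1.16, SE 0.28) and Cdt1 (0.71, SE 0.21) passed only adjusted over the list alone. Cholesterol synthesis and G2 and M held with an estimated correlation (adjusted p = 0.0027 and 0.01). Over the planned settings the cholesterol median ran from -1.32 to -0.52, the S phase median from 0.56 to 1.42 and the G2 and M median from 0.74 to 1.54. Cdc45 (0.68 to 1.26) and Cenpa (1.08 to 1.78) lost their calls without any of the 5 samples, 2 to 6, left out in turn. Calls were also lost without control sample 2 for Prc1 (1.31), Birc5 (1.44), Idi1 (-2.1) and Nsdhl (-1.89), without sample 3 for Rrm2 (1.44), Birc5 (1.32), Bub1b (0.99), Idi1 (-2.14) and Hsd17b7 (-1.51), and without sample 5 for Bub1b (1.16). Fitted on only the groups compared, Prc1 (1.79), Birc5 (1.38), Bub1b (1.23), Cenpa (1.43), Cdc45 (0.97) and Nsdhl (-2.23) did not pass. Cenpa did not pass with no background correction (1.39), the offset of 16 (1.44) or the authors' value table (1.12) either, nor Cdc45 with no filter (0.97).

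The largest single rises past the threshold from 24 to 48 h were those of the clock output gene Dbp (2.46, SE 0.55, 5.52-fold), the selenoprotein gene Selenoh (2.2, SE 0.24, 4.59-fold), the kinesin gene Kif15 (1.91, SE 0.25), Prc1 and the sulfotransferase gene Chst1 (1.74, SE 0.24). The largest falls were those of the cystine transporter gene Slc7a11 (-3.19, SE 0.45, 9.12-fold lower), an Actb probe (-2.89, SE 0.52, with 3 of 4 other probes of that gene opposite), the glutathione transferase genes Gsta3 (-2.75, SE 0.3) and Gstp1 (-2.52, SE 0.34), and the U6 small nuclear RNA Rnu6 (-2.46, SE 0.34). Mid1 also fell in the control from 24 to 48 h, by 1.37 (SE 0.28, limma adjusted p = 0.024), a call lost without control samples 2, 3, 5 or 6 (-1.42, -1.31, -1.39 and -1.26). The interferon response list was lower (23 of 29 negative, median -0.43, camera adjusted p = 2e-04, and 0.34 with an estimated correlation), where Ddx58 fell by 1.46 (SE 0.27) past the threshold and Irf9 (-0.9, SE 0.28), Gbp2 (-1.56, SE 0.54) and Gbp3 (-1.36, SE 0.49) did not pass. Calls were lost for Dbp without control sample 2, 3, 4 or 5 (2.25 to 2.51), for the Actb probe without 2 (-2.58) or 3 (-3.21), for Slc7a11 without 3 (-3.05) and for Ddx58 without 2 (-1.05). Dbp also lost its call with no background correction (2.12), cyclic loess (2.31), the authors' value table (2) and the trend and robust prior (2.46). Ddx58 lost it with median scaling (-1.07). With only the groups compared Ddx58 (-1.46), Chst1 (1.74), the Actb probe (-2.89) and Mid1 (-1.37) did not pass. NF-kB (median -0.59, adjusted p = 0.00091), stress response (-0.39, 0.0024), p53 (-0.28, 0.0024), YAP and serum response (-0.16, 0.018) and lipid storage lists (-0.26, 0.043) were lower by camera as well. Hypoxia and glycolysis (0.36, 0.012) and oxidative phosphorylation (0.17, 0.046) were higher. With an estimated correlation these 7 lists had adjusted p-values between 0.16 and 0.42. Over the planned settings the stress response median ran from -0.48 to 0.15 and the p53 median from -0.33 to 0.03. Without control sample 3 at 24 h the NF-kB (-0.46), p53 (-0.19), YAP (-0.15), lipid (-0.27), hypoxia (0.23) and oxidative phosphorylation (0.19) lists did not pass. Nor did hypoxia without sample 4 (0.2) or 5 (0.23), or lipid storage (-0.16) and oxidative phosphorylation (0.14) without sample 6. Oxidative phosphorylation also lost its call in 6 other settings (0.05 to 0.2). These were the offset of 16, cyclic loess, the authors' value table, the stricter filter, only the groups compared and array weights. Hypoxia lost it in the authors' value table (0.14). Lipid storage lost it with median scaling (0.19), the stricter filter (-0.26) and array weights (-0.1). YAP lost it with median scaling (0.18) and no filter (-0.1).

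In all, 63 probes (58 genes) rose and 56 (44 genes) fell from 24 to 48 h in the control by limma. The count was 23 and 19 without control samples 2 and 3 at 24 h, 33 and 77 without control samples 5 and 6 at 48 h, 17 with only the groups compared and 352 with array weights, and median scaling, which moves the median of all kept probes by 0.32, gave 1243 rises and 24 falls.

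Under anti-miR-135b, samples at 72 h differed from those at 24 h in interferon, cholesterol and glycolysis genes. Of 29 interferon response genes 26 were negative, with a median of -1.01 (camera adjusted p = 4.5e-10, and 0.21 with an estimated correlation), and 12 fell past the threshold over all probes, among them the kinase gene Eif2ak2, which encodes PKR (-2.2, SE 0.42, 4.58-fold lower), Gbp3 (-2.49, SE 0.49), the chemokine gene Cxcl10 (-1.61, SE 0.32) and Rsad2 (-2.45, SE 0.49). Cholesterol synthesis was negative in 17 of 18 genes, with a median of -1.21 (camera adjusted p = 2.9e-09, and 0.037 with an estimated correlation), and 9 fell past the threshold, including Hsd17b7 (-1.85, SE 0.26), Mvd (-1.69, SE 0.29), Hmgcs1 (-2.19, SE 0.37) and Cyp51 (-1.67, SE 0.3). Hypoxia and glycolysis genes were positive in 20 of 21, with a median of 0.8 (camera adjusted p = 1.5e-07, and 0.23 with an estimated correlation), and 8 rose past the threshold, including Ldha (1.4, SE 0.26), Aldoa (1.8, SE 0.34), the carbonic anhydrase gene Car9 (2.15, SE 0.47) and Ndrg1 (1.73, SE 0.38). The median of that list ran from 0.5 to 1.26 over the samples left out. In the stress response list 19 of 24 genes were negative, with a median of -0.43 (camera adjusted p = 1.9e-05, and 0.068 with an estimated correlation), and 5 fell past the threshold. Those included Slc7a11 (-4.94, SE 0.45, 30.6-fold lower), Chac1 (-3.54, SE 0.39, 11.7-fold lower) and the early stress genes Atf3 (-1.65, SE 0.22) and Ppp1r15a (-2.06, SE 0.33). Without anti-miR-135b sample 12 at 24 h calls were lost for Eif2ak2 (-2.01), Gbp3 (-2.49), Cxcl10 (-1.01), Rsad2 (-2.28), Mvd (-1.76), Cyp51 (-1.66), Ldha (1.01), Aldoa (1.86), Car9 (1.94), Ndrg1 (1.62) and Ppp1r15a (-1.46). Ndrg1 lost its call also without sample 11 (1.84) or 16 (1.52), and Hmgcs1 with median scaling (-1.93).

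By camera p53 targets (median -0.58, adjusted p = 0.0019), NF-kB genes (-0.72, 0.0025) and heat shock proteins (-0.48, 0.012) were also lower, and oxidative phosphorylation (0.45, 0.00064), cytosolic ribosomal proteins (0.29, 0.012) and G2 and M genes (0.3, 0.031) higher. With an estimated correlation these 6 lists had adjusted p-values from 0.068 to 0.37. The NF-kB list did not pass without anti-miR-135b sample 12 (-0.42) or 16 (-0.3), the ribosomal list without 11 (0.2) and the G2 and M list without 12 (0.19). The G2 and M list did not pass with no filter (0.21) or the stricter one (0.3), nor the ribosomal list with cyclic loess (0.2). The largest single rises were those of Dbp (3.64, SE 0.55, 12.5-fold), the purine enzyme gene Adssl1 (2.63, SE 0.67), the carbonic anhydrase gene Car12 (2.52, SE 0.43), Selenbp1 (2.47, SE 0.69) and the growth factor gene Pgf (2.28, SE 0.43). The largest falls were those of Slc7a11, Chac1, the chemokine gene Cxcl2 (-3.1, SE 0.58), the tropomyosin gene Tpm3 (-2.78, SE 0.56, its other probe opposite) and Rab32 (-2.71, SE 0.73). Adssl1 lost its call without any of samples 11, 12 and 16 to 18 (2.47 to 2.8), Selenbp1 without 11, 12, 16 or 17 (1.81 to 2.78) and Rab32 without 11, 12 or 16 (-2.96 to -2.14). Dbp (3.14), Car12 (2.41), Pgf (1.77), Cxcl2 (-2.44) and Tpm3 (-2.45) lost theirs without sample 12. With median scaling Adssl1 (2.67), Selenbp1 (2.42) and Rab32 (-2.72) did not pass. None of these 3 passed with the trend and robust prior (2.63, 2.47 and -2.71). Selenbp1 did not pass with no background correction (1.64) or in the authors' value table (1.65) either.

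By limma 540 probes (458 genes) rose and 485 (403 genes) fell from 24 to 72 h under anti-miR-135b. The count of 1025 became 474 and 25 without anti-miR-135b samples 11 and 12 at 24 h and 441, 677 and 665 without samples 16, 17 and 18 at 72 h, and it was 377 with median scaling and 2178 with array weights.

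The control course from 24 to 48 h and the anti-miR-135b course from 24 to 72 h used different samples and different chips. Of the 63 probes that rose in the first and the 540 in the second, 15 were shared where 2.6 are expected of independent lists, and of the 56 and 485 that fell, 42 were shared where 2.1 are expected. In 0 cases did a probe pass in opposite directions. Slc7a11, Mvd, Hsd17b7 and Dbp were among those past the threshold in both courses. Across probes, which are not independent replicates, the changes correlated with r = 0.48.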

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

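The tests of differences between times, of correlated genes, of chip and of the probe counts under other splits were chosen after the results were seen, and those of brightness and of the lists under other splits before their values were seen. With camera, the inhibitor difference of 2 lists was lower at 48 h than at 24 h. These are the interferon response (23 of 29 genes lower, median of the difference -0.38, adjusted p = 0.016) and the unfolded protein and integrated stress responses (18 of 24 lower, -0.36, adjusted p = 0.0053). At 72 h against 24 h, the stress responses (20 of 24 lower, -0.71, adjusted p = 6.4e-07), the interferon response (23 of 29 lower, -0.35, adjusted p = 0.0087) and miR-135 targets from other studies (9 of 12 lower, -0.31, adjusted p = 0.028) had a lower difference. Oxidative phosphorylation (27 of 34 higher, 0.24, adjusted p = 0.0039), the S phase list (17 of 20 higher, 0.26, adjusted p = 0.021) and cytosolic ribosomal proteins (19 of 23 higher, 0.18, adjusted p = 0.044) had a higher one. With an estimated correlation none of these 8 differences passed, with adjusted p-values from 0.071 to 0.57. Each subtracts the 24 h difference, which lies across chips, so a chip shift and a change with time cannot be told apart in any of them.

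The interferon list was higher under anti-miR-135b at 48 and 72 h. Array brightness does not give this difference. The slope of the list on brightness among samples of 1 group predicts -0.07 (SE 0.08), opposite to the observed 0.3. What stays open is the correlation between the list's genes, which the preset test takes as 0.01 where the estimate from the samples was 0.4, and with the estimate the adjusted p was 0.59. Chance could not be excluded, since 77 of 100 splits within both times called at least 1 list as the real one did, and the highest other called 8. Position on the chip cannot be told apart from the arm at either time, since the control samples took the earlier positions on both chips. A response to the inhibitor remains an untested candidate explanation.

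At 24 h the interferon, stress, NF-kB and oxidative phosphorylation lists differed between the arms by camera with its preset correlation. None passed with an estimated correlation (adjusted p = 0.28, 0.13, 0.56 and 0.067), so genes that vary together may give these calls. Brightness may give part of the interferon difference, as its slope predicts 0.21 (SE 0.23) of the observed 0.64, too wide to exclude. Chip and inhibitor cannot be told apart here, since the arms share no chip. The control samples on the second chip at 72 h lay below those on the first at 48 h in the interferon list (median -0.2, 22 of 29 genes lower), a shift opposite to the 24 h difference, but time can hide a chip effect of either sign. An early response to the inhibitor stays open as well.

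In the control, cholesterol synthesis genes were lower and G2 and M genes higher at 48 h than at 24 h. Brightness gives neither, predicting 0.12 (SE 0.09) where -1.14 was observed for the cholesterol list and 0.02 (SE 0.13) where 1 was observed for G2 and M. Both times lay on 1 chip. Position on the chip, culture density, serum and time after transfection all moved with the time points and were not tested.

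Other splits of the samples say nothing about chance for the probe counts, since each real count was 0 and every split gives at least that many. That holds for 10 of 10 splits at 48 h and at 72 h, which are also too few for a share under 0.05, and for 100 of 100 drawn splits for the mean of both times and for the difference between them. The highest other splits gave 10 probes at 48 h, 2 at 72 h, 400 for the mean and 7 for the difference. The split with 400 probes put samples 4, 5 and 13 at 48 h with 7, 8 and 16 at 72 h, which points to a structure of the samples other than the arms. Samples 4 and 13, 6 and 15, 7 and 16, and 9 and 18 stayed together, whose label numbers differ by 9. Their deviations from the group means correlated at 0.564, 0.499, 0.479 and 0.347. Samples 5 and 14 (0.081) and 8 and 17 (0.145) were parted. The splits took no account of this order.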

How the results depend on the processing

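Of the alternatives here, the block by label number and the fit without the least alike sample of each group of 3 were chosen after seeing the data, and where no cause is named the cause was not tested. The count of 0 at 24 h and for the difference between 48 and 72 h held under the 10 planned settings and without any sample. At 48 h it held under the planned settings and ranged from 0 to 4 without 1 sample. At 72 h it was 2 with no background correction, 2 with the authors' value table, 2 with array weights, and 0 to 1 without 1 sample. Over 48 and 72 h it was 8 with array weights and 0 to 6 without 1 sample. From 24 to 48 h the 119 probes became 1267 with median scaling, 17 with only the groups compared, 352 with array weights, 358 without the least alike sample of each group, and 19 to 119 without 1 sample. From 24 to 72 h the 1025 became 377 with median scaling, 2178 with array weights and 25 to 677 without 1 sample. The weights stopped short of their convergence tolerance. Control sample 5 at 48 h had a weight of 7.63, against 0.51 and 0.74 for samples 4 and 6. With array weights the mean of that group therefore rests mostly on 1 sample. Median scaling leaves the kept probes' medians at 0.32, -0.27 and 0.37 for 24 to 48 h, the inhibitor at 48 h and the difference between times, so it shifts calls in a direction by construction. Fewer samples leave less power when 1 of 2 at 24 h is removed.

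The number of lists past the threshold over 48 and 72 h was 1, and 2 with no background correction, 3 with the authors' value table, 2 with the stricter filter, 2 with only the groups compared, 4 with array weights, 0 with an estimated correlation, 0 with fry, and 0 to 4 without 1 sample. The interferon list over both times had a median of 0.28 in each of those last 2 tests (adjusted p = 0.59 and 0.53) and of 0.16 to 0.43 without 1 sample, its adjusted p running from 2.5e-14 to 0.59 over all alternatives. Of 21 named genes past the threshold from 24 to 48 h, 10 passed in each other setting and 7 without each sample, and of 24 from 24 to 72 h it was 20 and 5. With median scaling, the Mtch2 probes ILMN_1229238 and ILMN_2610204 stood at 0 and -0.28 at 48 h, and ILMN_1229238 at 0.09 at 72 h, where the medians of all kept probes moved by -0.27 and 0.08. Without control sample 9 the Mtch2 probes ILMN_1229238 and ILMN_2848583 stood at 0.04 and 0.04 at 72 h and without anti-miR-135b sample 16 at 0.03 and 0.07, of ranges -0.27 to 0.04 and -0.39 to 0.07. Ccl2 at 24 h ran from -0.04, without anti-miR-135b sample 12, to 1.41. Mid1 over both times ran from 0.38 to 0.99 in the 9 planned settings that kept its probe, which the stricter filter removed.

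The groups share no label number, so the labels give no pairs. Control numbers n and anti-miR-135b numbers n plus 9 deviate together unevenly, with correlations from 0.081 to 0.564 over 8 pairs, and 7 of 8 matched best. With 2 samples per arm, the 2 pairs at 24 h (0.101 each) mirror each other and make up 1 observation. As a hint from the data, a block on that order gave 13 probes at 48 h, 58 at 72 h, 100 over both, 12 at 24 h and 0 for the difference, and Mid1 over both times stayed at 0.76 with a limma adjusted p of 0.027. At 72 h Mid1 (1.09) and the Mtch2 probe ILMN_2610204 (1.05) then had a limma adjusted p of 0.028 each. Chip as a random block and the seed-match test were not run. Signal over background limits the dim probes, Mid1 among them, and the lack of detection p-values leaves that limit unmeasured.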

Other observations

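The tests of both hypotheses below were chosen, or had their bounds set, after the time courses were seen. The genes that fell most from 24 to 48 h in the control include Slc7a11, Gsta3 and Gstp1, which handle cystine and glutathione. A candidate explanation is a wider fall of targets of the oxidative stress factor NRF2. Of 27 other NRF2 targets written down for the test, 19 were measured, and 17 were lower at 48 h, with a median of -0.55 (camera p = 8.1e-09, p = 0.00065 with an estimated correlation). Hmox1 (-1.43, SE 0.37), Blvrb (-1.39, SE 0.48), Osgin1 (-1.16, SE 0.31) and Mafg (-1.14, SE 0.3) were lowest, none past the threshold over all probes there. Adjusted over the list alone, 8 of the 19 fell from 24 to 48 h. From 24 to 72 h under anti-miR-135b Hmox1 (-2.44, SE 0.37), Mafg (-1.51, SE 0.3), Gclc (-1.16, SE 0.23) and Taldo1 (-0.81, SE 0.22) fell past the threshold over all probes. Blvrb (0.08, SE 0.48) and Osgin1 (0.04, SE 0.31) did not fall there, and Cbr1 (0.7, SE 0.2) rose past it. From 24 to 72 h under anti-miR-135b the median was -0.18 with 11 of 19 lower (camera p = 0.0098, p = 0.054 with an estimated correlation), 5 falling and 2 rising adjusted over the list alone. Between the arms the same list had a median of -0.03 over 48 and 72 h and of -0.13 at 24 h, neither called by camera.

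Dbp, a gene driven by the circadian clock, rose 5.52-fold from 24 to 48 h in the control and 12.5-fold from 24 to 72 h under anti-miR-135b. If clock output as a whole moved, other clock genes might rise too. Of 15 written down, 9 were measured, and 7 were higher at 48 h in the control, with a median of 0.22. Under anti-miR-135b 6 of 9 were higher at 72 h, with a median of 0.36, and Tef rose past the threshold (1.59, SE 0.36). Per2 (1.31, SE 0.5) and Tef (0.86, SE 0.36) were highest at 48 h, not past the threshold. Between the arms at 24 h, which lie across chips, 8 of 9 were higher under anti-miR-135b, with a median of 0.21, past an unadjusted 0.05 with the preset correlation and not with an estimated one. Camera called neither course, and 9 genes, some of which peak at opposite times of day, are too few to exclude the hypothesis. The times of 24, 48 and 72 h also lie 24 h apart. A daily rhythm would be met near the same phase each time, so these samples can hardly show it.

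Mean levels of lists per sample were also compared between arms by exact permutation within 48 and 72 h, a test added after the camera results. Over 23 lists, mitochondrial carriers and outer membrane had a difference of 0.069. Its exact permutation p was 0.005, the smallest that 400 arrangements can give. For miR-135 targets from other studies the difference was -0.183, with an exact permutation p of 0.01. Neither passed once adjusted over the lists (0.12 for both). Adjusting over 23 lists leaves a lone list above 0.05 even at the smallest possible p. The adjusted values therefore cannot decide whether a lone list differs between the arms. The interferon response had a difference of 0.3 with an exact permutation p of 0.18.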
